A study of Mus musculus with 9 samples.

How the data were processed

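Prostate tissue was taken from mice of 3 genotypes at Srd5a2, the gene of the type II 5-alpha-reductase that converts testosterone to dihydrotestosterone: wild type (WT), heterozygous (Het) and null (KO). Each genotype is represented by 3 libraries, 9 in all. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and polyA-enriched cDNA libraries with inserts of 250 to 300 bp were made. Which lobes were taken, and the age of the mice, are not given in the sources used here. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program and strandedness are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and near-identical copies (such as Svs3a and Svs3b, or the haemoglobin genes) may share reads. Genotypes were taken from the library names in the sample descriptions. Replicate numbers 1 to 3 follow accession order and pair nothing. The labels do not say whether the libraries come from separate animals, so p-values measure the spread between these samples, which may be technical.

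The authors deposited a table of raw read counts per gene, whole numbers that are not normalised, with Ensembl identifiers, gene symbols and coordinates. They also deposited FPKM values per library, which are counts divided by gene length and by a scaled library total. Set against the plain totals, the deposited FPKM totals imply factors of 0.907 to 1.10. Divided by the RLE size factors (median of ratios, as in DESeq2) these give 1.016 in each of the 9 libraries, so the FPKM values carry that scaling. A further deposited table holds FPKM means per genotype. These matched the means of the libraries' values to within 7.3e-12, and it was not used further. Of the 54532 gene identifiers, 54495 were found in GENCODE vM21, and 98.3% of those had the same coordinates there. Coordinates are given as in the deposited table, on GRCm38 (mm10).

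Counts were tested with edgeR 4.0.16 in R 4.3.3. All 9 libraries entered 1 quasi-likelihood model (robust) with genotype as the only factor, after TMM normalisation. The filterByExpr rule kept 16836 of the 54532 genes, and 25767 had at least 1 count. Contrasts were KO against WT, Het against WT and KO against Het, together with a linear term for the number of null alleles (0, 1 and 2). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and intervals are at 95%. CPM values use TMM-scaled library sizes. A gene with a count of 0 in every library of a group is given a bound from 3 counts over that group. Such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

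Gene lists were fixed before the data were examined. There are 31, of 12 to 48 genes each: androgen-responsive genes; steroid metabolism and receptors; Wnt ligands, receptors and antagonists; Wnt/beta-catenin transcription factors and target genes; the IGF axis; stromal growth factors of the prostate; prostate secretory luminal cells; proximal luminal cells; basal epithelial cells; neuroendocrine cells; smooth muscle; fibroblasts and extracellular matrix; endothelium; macrophages and dendritic cells; neutrophils and acute inflammation; T and NK cells; B and plasma cells; interferon response; cell proliferation; secretory pathway and unfolded protein response; fatty acid and cholesterol synthesis; oxidative phosphorylation; apoptosis and cell cycle arrest; immediate early and heat shock genes; seminal vesicle; epididymis and vas deferens; urothelium; skeletal muscle; adipocytes; nerve and Schwann cells; and blood. The 29 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Members were also adjusted over the list alone. A list score is the mean log2 CPM of the list's tested genes in a library, less the mean over the 9 libraries.

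Genes named in the text follow a rule fixed before the data were examined. Srd5a1, Srd5a2, Srd5a3, Wnt5a, Lef1, Igf1 and Igf1r are always given. Some results that the rule names are not reported here. Where under 5 genes pass in a comparison, the 5 with the smallest p in each direction are given as values that did not pass, and up to 4 members with the smallest p are given per list. Other genes (Sbp, Spink1, Crabp1, Svs2, Svs5, Tpsb2, Cpa3, Kit, the Gsdmc genes, Ehd3 and Capn13) were chosen after their values were seen.

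Alternatives fixed beforehand were other normalisations (DESeq2 size factors, upper quartile, and library sizes without genes over 1% of a library), no low-count filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom with and without library quality weights, 1 surrogate variable (sva 3.50.0), limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a fold threshold, the 6 libraries of a comparison alone, and each library left out in turn. Added after seeing the data were 4 covariates (log2 CPM of Sbp, the seminal vesicle score, the skeletal muscle score and the number of genes detected) and a fit without WT libraries 1 and 3 and Het library 2. Some of these covariates themselves differ between genotypes. A call that ended with such a covariate may have lost a genotype difference, and does not show that other tissue accounts for the list.

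On simulated counts with the means, library sizes and dispersions of these data, with 50 genes changed at each fold in KO against WT, edgeR recovered 8%, 40%, 60% and 80% of genes changed 2-, 4-, 8- and 16-fold among 16836 genes, with 4 false calls. DESeq2 recovered 16%, 62%, 78% and 86% with 48 false calls. In a simulated list test, camera called the shifted set and 0 of 30 unchanged sets. Genes were drawn independently in these simulations, while estimated correlations within the tested lists reached 0.9 (smooth muscle). The list test therefore does not show how often camera calls unchanged lists whose genes move together. Chance agreement between the contrasts that share the WT libraries was taken from 20 simulations of 3 unchanged groups, each gene drawn independently around the mean of all libraries. That simulation was settled after the data were seen: a first version had kept the WT libraries fixed at their own mean, which removed the deviation the contrasts share, and was replaced for that reason.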

Results

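Bulk RNA-seq compared the prostates of WT, Het and KO mice, with 3 libraries per genotype. The series title names stromal SRD5A2, prostate growth and a WNT5A-LEF1-IGF1 route in benign prostatic hyperplasia, so the contrasts ask what loss of 1 or both Srd5a2 alleles does to the prostate transcriptome and to those genes. Total counts ran from 16233392 to 24017791 per library. At equal depth, 20392, 19626 and 17875 genes had a count in the WT libraries, 17748, 17155 and 16834 in the Het libraries, and 20097, 20380 and 20338 in the KO libraries. Pairs of libraries correlated at 0.914 to 0.937 within WT, 0.818 to 0.894 within Het and 0.947 to 0.957 within KO (Pearson r of log2 CPM across genes, which are not independent replicates). No pair of libraries was close to a duplicate, since the lowest chi-square per degree of freedom between any 2 was 42.4.

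Secretory genes differed between libraries of 1 genotype by several orders of magnitude. Sbp, which encodes spermine-binding protein, a secretion of the rodent ventral prostate, stood at 0.993 and 16 CPM in WT libraries 1 and 3 and at 7.26 CPM in Het library 2, against 34300 to 144000 CPM in the other 6. Spink1, a secreted trypsin inhibitor, and Crabp1, a retinoic acid carrier, followed it: Spink1 was at 0.105, 197 and 6.75 CPM in those 3 libraries and at 4790 to 18800 CPM elsewhere. Svs2, a seminal vesicle secretory protein, ran from 3900 CPM in Het library 1 to 230000 CPM in Het library 2. Svs1 was at 2460 to 7660 CPM in the KO libraries, at 2.40, 254 and 2480 CPM in WT libraries 1 to 3, and at 0 to 12.3 CPM in the Het libraries. The skeletal muscle score was highest in KO library 2 (5.04), with 2.40 in KO library 3, 1.89 in WT library 3 and 1.47 in KO library 1, and below -1.5 in the other 5.

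**Figure D1:**
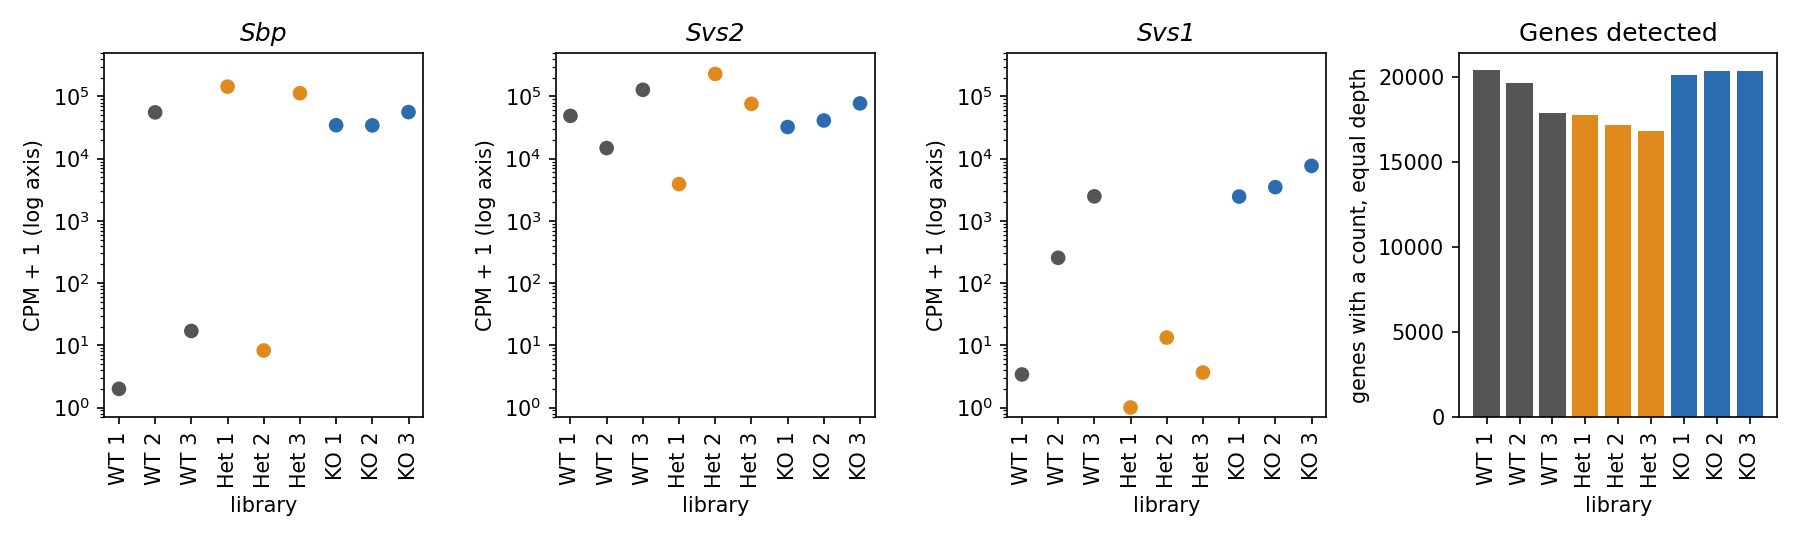
CPM plus 1 of Sbp, Svs2 and Svs1 on log axes and the number of genes with a count at equal depth on a linear axis, for each of the 9 libraries (grey WT, orange Het, blue KO). Sbp was at 16 CPM or lower in WT libraries 1 and 3 and Het library 2, and the Het libraries had 16834 to 17748 genes detected against 20097 to 20380 in KO.

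Srd5a2 (ENSMUSG00000038541, chromosome 17, 74016955 to 74047916) was lowest in the libraries labelled KO, at 0.933, 0.511 and 1.15 CPM, against 2.30, 5.50 and 8.81 CPM in WT and 3.67, 5.19 and 2.37 CPM in Het. Between 9 and 22 reads per KO library still fell on the gene, and which part of it is deleted is not given in the sources used here. The log2 fold change in KO against WT was -2.67 (SE 0.62, 95% interval -4.06 to -1.28, n = 3 per group), which did not pass over all genes in edgeR (adjusted p = 1) and passed when adjusted over the list alone, the 4 genes Srd5a2, Wnt5a, Lef1 and Igf1 (adjusted p = 0.00663). DESeq2 also called it over all genes (adjusted p = 0.0397). Against Het, the KO value was -2.11 (SE 0.61, edgeR adjusted p = 0.64, and 0.0261 adjusted over the list alone). Het and WT differed by -0.56 (SE 0.58, edgeR adjusted p = 0.82), less than the spread between libraries.

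The genes of the proposed route did not pass in any comparison. Wnt5a (chromosome 14, 28504750 to 28527448), a secreted Wnt ligand, averaged 19.7 ± 0.217 CPM in WT, 24.6 ± 16.3 in Het and 25.8 ± 7.12 in KO (SD, n = 3 each). Lef1 (chromosome 3, 131110471 to 131224356), a transcription factor that acts with beta-catenin, averaged 4.36 ± 2.31, 5.29 ± 4.98 and 3.96 ± 1.71 CPM. Igf1 (chromosome 10, 87858265 to 87937042), the insulin-like growth factor, averaged 20.9 ± 4.82, 15.4 ± 7.12 and 26.1 ± 4.07 CPM. In KO against WT their log2 fold changes were 0.39 (95% interval -0.78 to 1.57), -0.14 (-1.70 to 1.43) and 0.32 (-0.38 to 1.02), with edgeR adjusted p of 1 over all genes and 0.625, 0.848 and 0.625 adjusted over the list alone. All 3 KO libraries lay above the WT libraries for Wnt5a, at 20.2, 23.4 and 33.8 against 19.5, 19.9 and 19.5 CPM, and the intervals of all 3 genes leave room for changes of either sign. Igf1 in KO against Het was 0.76 (SE 0.32, 0.0761 adjusted over the list alone). With the added covariates the sign of all 3 KO against WT values turned under at least 1: Wnt5a to -0.39 with the seminal vesicle score, Lef1 to 0.58 and Igf1 to -0.01 with Sbp.

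Of the other genes fixed in advance, Srd5a1 (chromosome 13, 69573449 to 69611442), the type I isoenzyme, differed from WT by 0.88 (SE 0.50) in Het and 0.39 (SE 0.50) in KO. Srd5a3 (chromosome 5, 76140271 to 76155504) differed by -0.02 (SE 0.24) and -0.24 (SE 0.24), and Igf1r (chromosome 7, 67952827 to 68233668), the IGF1 receptor, by 0.45 (SE 0.36) and 0.18 (SE 0.36). None of these passed in edgeR.

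**Figure D2:**
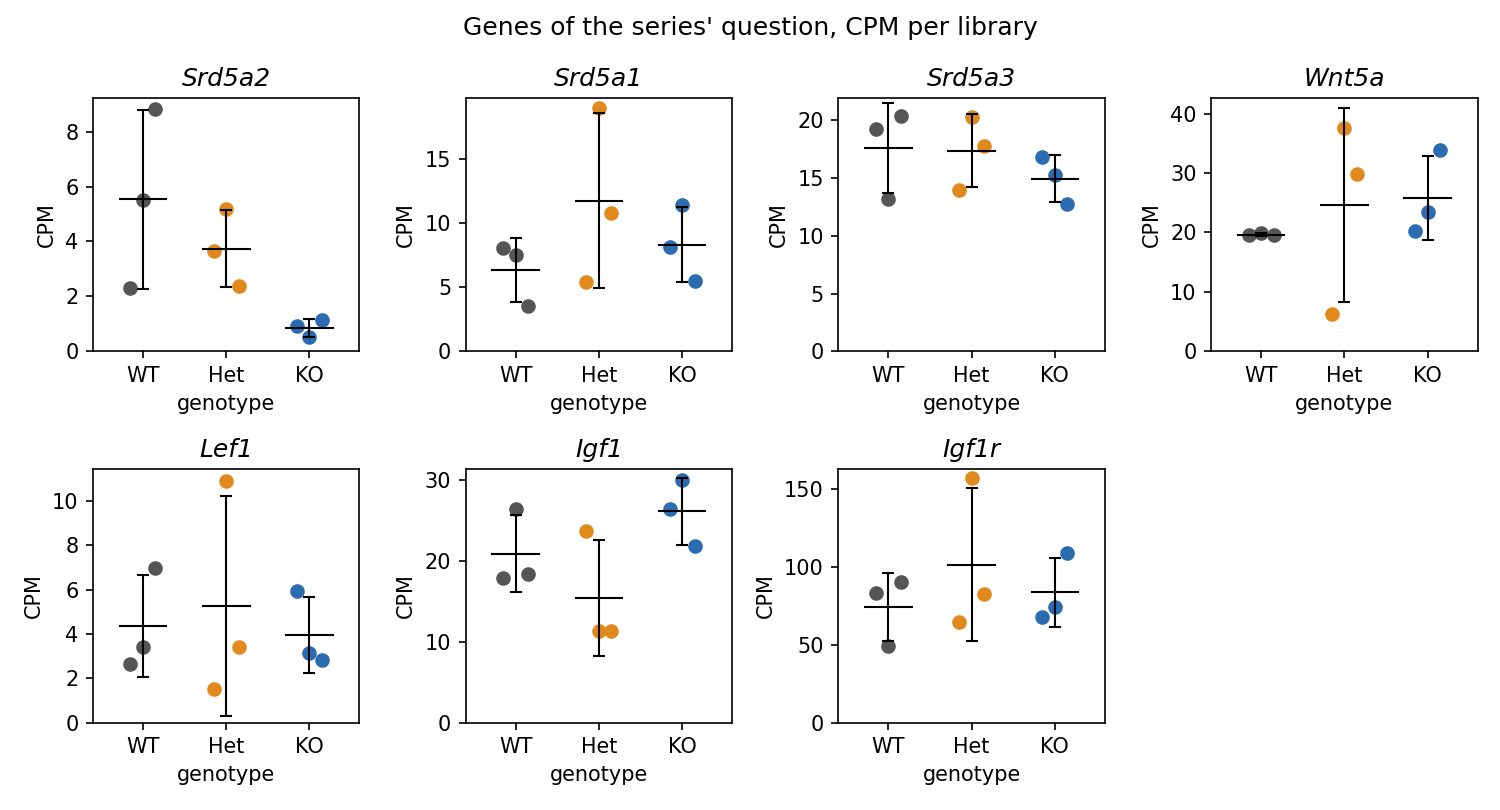
CPM of Srd5a2, Srd5a1, Srd5a3, Wnt5a, Lef1, Igf1 and Igf1r by genotype on linear axes from 0; points are libraries, horizontal bars group means and error bars 1 SD (n = 3). The 3 KO libraries lie between 0.511 and 1.15 CPM for Srd5a2, below every WT and Het library, while the genotypes overlap for Lef1.

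In KO against WT, the proximal luminal list was higher and the secretory pathway and unfolded protein response list lower by camera (adjusted p = 7.2e-05 and 4.1e-10, and adjusted p = 0.46 for both with an estimated correlation). No single gene passed over all genes in edgeR, and both list calls ended with the skeletal muscle score as a covariate, the proximal luminal call also with the seminal vesicle score. Wfdc2, a secreted member of the whey acidic protein family, averaged 43.8 ± 6.17 CPM in KO and 8.24 ± 1.55 in WT (SD, n = 3), a log2 fold change of 2.41 (SE 0.40). Krt4, a keratin of stratified epithelia, averaged 86.8 ± 51.7 against 10.9 ± 4.18 CPM (2.99, SE 0.51). Herpud1, an endoplasmic reticulum-associated degradation protein, averaged 294 ± 15.5 against 579 ± 160 CPM (-0.98, SE 0.19), and Ddit3, the stress transcription factor CHOP, 16.4 ± 3.91 against 41.7 ± 14.3 CPM (-1.35, SE 0.28). Other genes with the smallest p were Clca1, a secreted protein of mucous cells (3.82, SE 0.85), Rapgef4, a cAMP-activated exchange factor (1.65, SE 0.36), and Aspa, aspartoacylase (2.16, SE 0.48), on the higher side, and Cnbd2 (-1.29, SE 0.28), Fam199x (-0.89, SE 0.20) and Srd5a2 on the lower.

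None of these genes passed over all genes: edgeR called 0 of 16836 genes in KO against WT (lowest adjusted p = 0.9996). At an unadjusted p under 0.05 were 601 genes (371 higher, 230 lower), where uniform p-values would give 842. The spread around that figure for genes that move together was not tested. DESeq2 called 14 (11 higher, 3 lower), among them Wfdc2, Krt4, Rapgef4, Clca1, Aspa, Herpud1, Ddit3 and Srd5a2, and limma voom 0. Adjusted over the list alone, 3 of 15 proximal luminal members passed as higher (among them Wfdc2 and Krt4) and 3 of 24 secretory pathway members as lower (Herpud1, Ddit3 and Dnajb9, a chaperone partner). Slc30a2, a zinc transporter of the secretory luminal list, passed as lower (-0.98, SE 0.23, adjusted p = 0.04 over the list alone), as did Srd5a2 in the steroid list (adjusted p = 0.038). No other list had a member that passed.

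Camera called 15 of 29 lists in KO against WT, 13 higher and 2 lower. The lower lists were the secretory pathway and unfolded protein response, with all 24 members negative (median log2 fold change -0.31, adjusted p = 4.1e-10, and adjusted p = 0.46 with an estimated correlation), and cell proliferation, with 27 of 30 members negative (median -0.56, adjusted p = 3.7e-08, and adjusted p = 0.46 with an estimated correlation). In the latter Ube2c and Aurka, which act in mitosis, had -1.25 (SE 0.46) and -1.10 (SE 0.40). The proliferation scores were -1.07, -0.19 and 0.55 in the KO libraries and 0.19, 0.80 and 0.43 in the WT libraries, and the mean difference of -0.71 was -0.29 without KO library 1 and -1.11 without KO library 3. Without WT library 1 the basal and interferon lists were not called, nor with the skeletal muscle score as a covariate or without the 3 libraries low in Sbp. The basal call also ended with the seminal vesicle score and the interferon call with Sbp. Proximal luminal cells were higher (13 of 15 positive, median 0.88, adjusted p = 7.2e-05, and adjusted p = 0.46 with an estimated correlation), as were basal epithelial cells (13 of 14 positive, median 0.50, adjusted p = 0.0021, and adjusted p = 0.47 with an estimated correlation), with the basal keratin genes Krt15 at 0.95 (SE 0.35) and Krt5 at 0.75 (SE 0.43). Interferon response genes were higher (17 of 23 positive, median 0.61, adjusted p = 0.00023, and adjusted p = 0.46 with an estimated correlation), with Usp18 at 1.63 (SE 0.50) and Ifit3 at 1.28 (SE 0.44).

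Signalling lists, the fibroblast list and the T and NK cell list were also higher in KO against WT. Wnt ligands, receptors and antagonists had 28 of 40 members positive (median 0.29, camera adjusted p = 0.033, and adjusted p = 0.47 with an estimated correlation), led by the Wnt-binding proteins Sfrp2 (1.24, SE 0.41) and Sfrp5 (1.31, SE 0.57). The IGF axis had 15 of 19 positive (median 0.18, adjusted p = 0.038, and adjusted p = 0.46 with an estimated correlation). Its leading members were binding proteins of the growth factor, Igfbp3 (1.43, SE 0.40) and Igfbp5 (0.95, SE 0.33), not Igf1. Stromal growth factors had 23 of 31 positive (median 0.35, adjusted p = 0.022, and adjusted p = 0.47 with an estimated correlation), with Gli1 at 1.39 (SE 0.54) and Shh, the hedgehog ligand, at 1.14 (SE 0.49). Fibroblasts and extracellular matrix had 23 of 26 positive (median 0.36, adjusted p = 0.0044, and adjusted p = 0.69 with an estimated correlation), and T and NK cells 10 of 12 (median 0.66, adjusted p = 0.033, and adjusted p = 0.47 with an estimated correlation). Each of these calls could be ended by leaving out 1 library. Of the 9 omissions of 1 library, 4 ended the Wnt call (WT 1, WT 2, KO 1 or KO 3), 4 the IGF axis call (WT 1, Het 1, Het 2 or KO 2) and 6 the T and NK cell call (WT 1, any Het library, KO 2 or KO 3). The stromal growth factor and fibroblast calls ended without WT 1 or KO 1. With the seminal vesicle score, the skeletal muscle score, or without the 3 libraries low in Sbp, all 5 calls ended. With Sbp as a covariate the IGF axis, fibroblast and T and NK cell calls ended, and with voom quality weights the T and NK cell call.

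Markers of other tissues were also higher in KO against WT. Skeletal muscle genes were positive in 21 of 21 (median 3.43, camera adjusted p = 1e-13, and adjusted p = 0.46 with an estimated correlation), as were nerve and Schwann cell genes in 20 of 20 (median 1.52, adjusted p = 3.4e-07, and adjusted p = 0.46 with an estimated correlation) and neuroendocrine genes in 8 of 8 (median 1.99, adjusted p = 0.00054, and adjusted p = 0.47 with an estimated correlation). Seminal vesicle genes were positive in 9 of 12 (median 1.89, adjusted p = 0.0044, and adjusted p = 0.62 with an estimated correlation) and urothelium genes in 8 of 11 (median 1.08, adjusted p = 0.029, and adjusted p = 0.61 with an estimated correlation). The seminal vesicle call ended without WT library 1 or 2, and the urothelium call without WT library 3 or KO library 1. With the seminal vesicle score as a covariate the nerve, neuroendocrine and urothelium calls ended, and with the skeletal muscle score that of seminal vesicle. A list adjusted for its own score loses its difference by construction, which is not read as a loss here. The urothelium call also ended with genes detected as a covariate, without the 3 libraries low in Sbp, and with voom quality weights. Fry called 0 of the 29 lists. Without WT library 1 camera called 8 lists in place of 15, and with the skeletal muscle score as a covariate 6, among which the proximal luminal list was not.

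The other 14 lists were not called in KO against WT (camera adjusted p from 0.055 to 0.81). Endothelium had a median of 0.40 (adjusted p = 0.055), B and plasma cells 1.02 (0.33), adipocytes 0.01 (0.28), fatty acid and cholesterol synthesis 0.12 (0.36), apoptosis and cell cycle arrest -0.05 (0.40) and immediate early and heat shock genes -0.08 (0.43). At an adjusted p of 0.57 stood steroid metabolism and receptors (median 0.01), prostate secretory luminal cells (0.24), macrophages and dendritic cells (-0.08) and oxidative phosphorylation (0.05). Blood had a median of -0.09 (0.71), smooth muscle 0.08 (0.75) and androgen-responsive genes 0.01 (0.81). For Wnt/beta-catenin transcription factors and target genes the median (-0.01) and the test (higher, 0.75) differed in sign. Of the lists with too few tested genes for a test, neutrophils and acute inflammation had 3 (Ptgs2 -0.80, SE 1.86; Tnf 0.47, SE 1.33; Csf3r 0.87, SE 1.16) and epididymis and vas deferens 4 (Crisp1 -0.63, SE 2.03; Defb1 -0.27, SE 0.24; Adam28 -0.38, SE 0.35; Wfdc10 -1.34, SE 1.27), each with an edgeR adjusted p of 1.

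**Figure D3:**
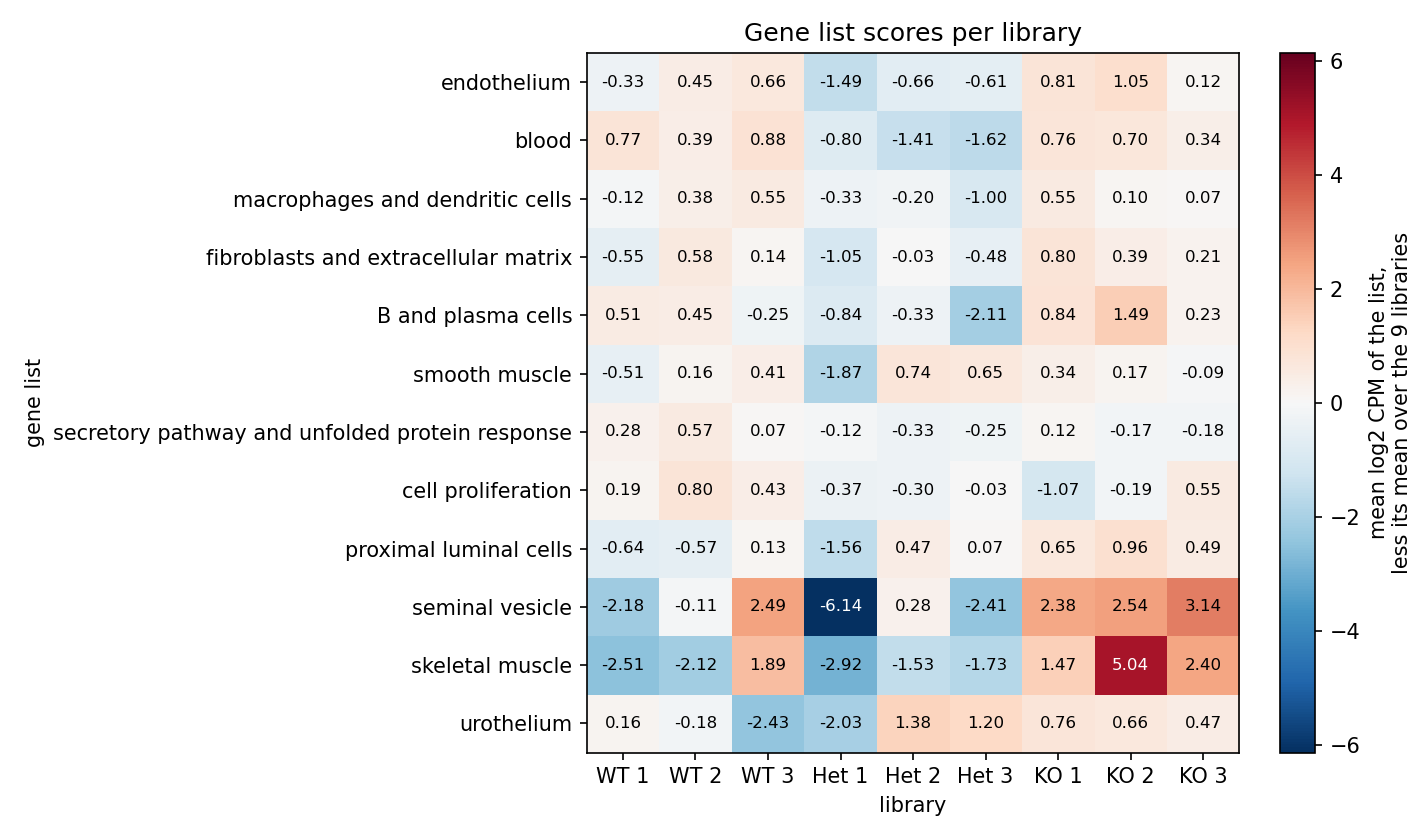
Scores of 12 gene lists in each library: the mean log2 CPM of the list's tested genes less its mean over the 9 libraries, from blue (lower) to red (higher). The 3 Het libraries have the lowest blood and endothelium scores, and the skeletal muscle score reaches 5.04 in KO library 2.

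In Het against WT, the endothelium and blood lists were lower by camera (adjusted p = 2.5e-05 and 3.2e-05, and adjusted p = 0.59 and 0.094 with an estimated correlation), while no single gene passed over all genes. The endothelium call ended with the seminal vesicle score as a covariate and with voom quality weights. Plvap, a protein of endothelial fenestrae, averaged 3.41 ± 1 CPM in Het and 11.6 ± 3.33 in WT (SD, n = 3; log2 fold change -1.76, SE 0.36), Lyve1, a lymphatic endothelial receptor, 0.936 ± 0.352 against 6.67 ± 3.58 CPM (-2.82, SE 0.57), and Vwf, von Willebrand factor, 3.46 ± 1.79 against 15.3 ± 0.567 CPM (-2.14, SE 0.46). The haemoglobin gene Hba-a1 averaged 7.46 ± 2.47 against 27.6 ± 5.87 CPM (-1.89, SE 0.32). Mcpt4 and Cma1, proteases of mast cells, averaged 3.48 and 2.47 CPM in WT and had 0 reads in each Het library, at least 68-fold and 48-fold lower against a floor of 3 counts over the group. These bounds cover counting error alone: of the 2383 genes averaging 1 to 3 CPM, 10.7% to 12.4% were at 0 in each Het library, against 7.3% in WT library 3 and 0.126% to 2.06% in the other 5. Slc30a2, the zinc transporter, was at 52.9 ± 10.6 against 146 ± 36.9 CPM (-1.47, SE 0.23), and Gtpbp2, a GTP-binding protein, at -0.85 (SE 0.14).

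Higher in Het were Rab11fip1, an effector of endosome recycling, at 201 ± 18.5 against 106 ± 13.0 CPM (SD, n = 3; log2 fold change 0.93, SE 0.15), Myo1e, a membrane-bound myosin (0.97, SE 0.17), Bmpr1b, a bone morphogenetic protein receptor (1.40, SE 0.27), Acpp, prostatic acid phosphatase (1.27, SE 0.26), and Cab39l (0.71, SE 0.15). None passed over all genes, as edgeR called 0 genes in Het against WT (lowest adjusted p = 0.38). At an unadjusted p under 0.05 there were 1522 genes (577 higher, 945 lower), where uniform p-values would give 842. Simulated unchanged groups gave medians of 382 higher and 367 lower, with genes drawn independently. The spread for genes that move together was not tested. DESeq2 called 205 (54 higher, 151 lower) and voom with library quality weights 699 (121 higher, 578 lower), while limma voom called 0. Without Het library 1 edgeR called 258 genes (56 higher, 202 lower).

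Camera called 8 of 29 lists in Het against WT, 7 lower and 1 higher. Blood was lower in 7 of 7 members (median log2 fold change -1.89, adjusted p = 3.2e-05, and adjusted p = 0.094 with an estimated correlation), endothelium in 14 of 15 (median -1.07, adjusted p = 2.5e-05, and adjusted p = 0.59 with an estimated correlation), and macrophages and dendritic cells in 16 of 17 (median -0.72, adjusted p = 3.2e-05, and adjusted p = 0.59 with an estimated correlation). B and plasma cells were lower in 6 of 8 (median -1.26, adjusted p = 0.0043, and adjusted p = 0.59 with an estimated correlation), and fibroblasts and extracellular matrix in 23 of 26 (median -0.51, adjusted p = 0.0018, and adjusted p = 0.84 with an estimated correlation). Adjusted over the list alone, the members that passed as lower were 3 haemoglobin genes (Hba-a1, Hbb-bs and Hbb-bt), 4 endothelial genes (Lyve1, Plvap, Vwf and Emcn), the antibody gene Igha and Derl3 of the B and plasma cell list, and the matrix-associated genes Pi16 (-1.45, SE 0.35) and Mfap5 (-2.44, SE 0.59). Derl3 averaged 178 CPM in WT, against 17.1 CPM for the antibody gene Ighm, and which cells its reads come from was not tested. Of the macrophage members 0 passed, with the complement gene C1qa at -0.95 (SE 0.29). The fibroblast call ended without WT library 2 or Het library 1, and the B and plasma cell call without Het library 1 or 3. With the seminal vesicle score as a covariate both ended, and the B and plasma cell call also with genes detected, without the 3 libraries low in Sbp, and with voom quality weights.

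Secretory pathway and proliferation genes were lower in Het against WT as well. The secretory pathway and unfolded protein response had 21 of 24 members negative (median -0.50, camera adjusted p = 1.2e-06, and adjusted p = 0.59 with an estimated correlation), and 13 passed as lower adjusted over the list alone. The list was not called with the number of genes detected as a covariate. Among these were Ddit3 (-1.51, SE 0.28), Herpud1 (-0.77, SE 0.19), the chaperone gene Hsp90b1 (-0.81, SE 0.22) and Manf (-0.80, SE 0.22). Cell proliferation had 24 of 30 negative (median -0.67, adjusted p = 0.0028, and adjusted p = 0.84 with an estimated correlation), with Mki67, the Ki-67 antigen, at -1.37 (SE 0.44) and 0 members passing. Fatty acid and cholesterol synthesis was the higher list, with 21 of 26 positive (median 0.36, adjusted p = 0.011, and adjusted p = 0.84 with an estimated correlation), led by Fdft1, squalene synthase (0.47, SE 0.14), and Srebf1 (0.46, SE 0.15). The proliferation call ended without Het library 1 or with the seminal vesicle score. That of fatty acid and cholesterol synthesis ended without WT library 3 or Het library 3, and with Sbp, the seminal vesicle score or the skeletal muscle score.

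In the uncalled secretory luminal list of Het against WT, Slc30a2 and Pbsn, the androgen-regulated secretory protein probasin (-1.49, SE 0.42), passed as lower and Acpp as higher when adjusted over the list alone. Bmpr1b passed as higher among androgen-responsive genes (adjusted p = 0.016 over the list alone). Medians of the 21 uncalled lists lay between -1.85 (skeletal muscle) and 1.64 (urothelium), with camera adjusted p from 0.059 to 0.97. The median and the test differed in sign for stromal growth factors, secretory luminal cells, smooth muscle, and T and NK cells. Fry called 1 list, blood (adjusted p = 0.0038). At equal depth each Het library had fewer genes detected (16834 to 17748) than any WT or KO library (17875 or more). With the number of genes detected as a covariate camera called 13 lists, though not the secretory pathway or B and plasma cell list. Without WT library 1 it also called 13. With the seminal vesicle score as a covariate 5 lists were called and edgeR called 285 genes.

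In KO against Het, the endothelium and blood lists were higher by camera (adjusted p = 5.4e-10 and 2.2e-05, and adjusted p = 0.31 and 0.086 with an estimated correlation), while no single gene passed over all genes. The endothelium call ended with the seminal vesicle or the skeletal muscle score as a covariate. Both scores parted these groups without overlap. The seminal vesicle score was 2.38 to 3.14 in KO and -6.14 to 0.28 in Het, the skeletal muscle score 1.47 to 5.04 and -2.92 to -1.53. Calls of this contrast that ended with either score may therefore have lost a genotype difference. Plvap averaged 16.9 ± 4.89 CPM in KO and 3.41 ± 1 in Het (SD, n = 3; log2 fold change 2.31, SE 0.37), Hba-a1 30 ± 8.86 against 7.46 ± 2.47 CPM (2.01, SE 0.32), and Clec3b, the plasminogen-binding protein tetranectin, 37.7 ± 18.8 against 7.91 ± 1.13 CPM (2.25, SE 0.36). Mcpt4 averaged 3.36 CPM in KO, at least 65-fold above Het, a bound for counting error alone as before. Clca1 averaged 8.67 ± 6.15 CPM in KO and 0.036 ± 0.0624 in Het. On the lower side were Rab11fip1 (-0.74, SE 0.15), Hacd2, an enzyme of fatty acid elongation (-0.75, SE 0.16), Myo1e (-0.78, SE 0.17), Cab39l (-0.64, SE 0.15) and Mia2, which acts in export from the endoplasmic reticulum (-0.57, SE 0.14).

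As in the other contrasts, edgeR called 0 genes in KO against Het (lowest adjusted p = 0.3107), with 1048 at an unadjusted p under 0.05 (744 higher, 304 lower). DESeq2 called 169 (156 higher, 13 lower) and limma voom 0. Without Het library 1 edgeR called 18 genes. The seminal vesicle score as a covariate gave 105 calls (77 higher, 28 lower).

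Camera called 10 of 29 lists in KO against Het, all higher. Endothelium (median 1.62, adjusted p = 5.4e-10, and adjusted p = 0.31 with an estimated correlation), fibroblasts and extracellular matrix (0.91, adjusted p = 4.9e-09, and adjusted p = 0.48 with an estimated correlation), blood (1.99, adjusted p = 2.2e-05, and adjusted p = 0.086 with an estimated correlation), macrophages and dendritic cells (0.68, adjusted p = 3e-05, and adjusted p = 0.48 with an estimated correlation) and B and plasma cells (2.22, adjusted p = 3e-05, and adjusted p = 0.27 with an estimated correlation) were lists also called lower in Het against WT. Both contrasts use the same Het libraries, so these calls are not separate evidence. Adjusted over the list alone, 11 of 15 endothelial, 9 of 26 fibroblast, 3 of 7 blood, 2 of 8 B and plasma cell and 0 of 17 macrophage and dendritic cell members passed as higher. With the seminal vesicle score as a covariate the endothelium, fibroblast, macrophage and B and plasma cell calls ended. The endothelium and macrophage calls also ended with the skeletal muscle score, and the B and plasma cell call with genes detected. The collagen gene Col5a1 had 1.45 (SE 0.30) and Dcn, decorin, 0.81 (SE 0.22).

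Of the epithelial lists, proximal luminal and basal cells were called higher in KO against Het and secretory luminal cells were not (median 0.08, camera adjusted p = 0.44). Both calls ended without Het library 1 (adjusted p = 0.46 and 0.23), whose scores were -1.56 and -1.29 against 0.47 and 0.07, and 0.09 and -0.06, in the other Het libraries, and with the seminal vesicle or skeletal muscle score as a covariate. The proximal luminal call also ended with voom quality weights. Proximal luminal cells (median 0.25, camera adjusted p = 0.0021, and adjusted p = 0.48 with an estimated correlation) had 4 members that passed adjusted over the list alone, among them Krt4 (2.80, SE 0.50), Aldh1a3, a retinoic acid-forming enzyme (1.71, SE 0.44), and Ly6a (1.21, SE 0.38). Basal epithelial cells (median 0.40, adjusted p = 0.00045, and adjusted p = 0.55 with an estimated correlation) had 3, Krt15 (1.54, SE 0.35), the desmosome gene Pkp1 (1.47, SE 0.38) and Dapl1, which had 0 reads in Het and was at least 25-fold higher (counting error alone). A further 3 tissue lists were called: skeletal muscle (median 5.87, adjusted p = 2.3e-13, and adjusted p = 0.36 with an estimated correlation) with 10 of 21 members passing, seminal vesicle (median 2.63, adjusted p = 0.00011, and adjusted p = 0.58 with an estimated correlation) with 5 of 12, and nerve and Schwann cells (median 0.33, adjusted p = 0.025, and adjusted p = 0.68 with an estimated correlation) with 0 of 20. The seminal vesicle call ended without Het library 1, and the nerve call without Het library 1 or KO library 2. The skeletal muscle and nerve calls ended with the seminal vesicle score as a covariate, the seminal vesicle and nerve calls with the skeletal muscle score, the nerve call also with genes detected, and the seminal vesicle and nerve calls with voom quality weights. In the uncalled IGF axis, Igfbp3 (1.84, SE 0.40), Igfbp5 (1.49, SE 0.34) and Igfbp4 (1.18, SE 0.31) passed as higher and Pappa2, a protease that cleaves such binding proteins (-1.20, SE 0.37), as lower, adjusted over the list alone.

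Fry called 2 lists in KO against Het, blood (adjusted p = 0.0046) and B and plasma cells (adjusted p = 0.042). The 19 uncalled lists had medians between -0.59 and 0.52 and camera adjusted p from 0.073 to 0.75. The median and the test differed in sign for the IGF axis, smooth muscle, cell proliferation and urothelium. List medians did not move when members at 0 in a whole group were set at their bound (5.87 for skeletal muscle and 0.40 for basal epithelial cells in KO against Het). Camera called 4 lists with the seminal vesicle score as a covariate and 6 with the skeletal muscle score.

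A linear trend over 0, 1 and 2 null alleles gave 0 calls in edgeR (lowest adjusted p = 0.9997), with 519 genes at an unadjusted p under 0.05 (328 higher, 191 lower), 4 calls by DESeq2 (3 higher, 1 lower) and 0 by limma voom. Srd5a2 had a slope of -1.32 per null allele (SE 0.35, edgeR adjusted p = 1). Fold changes of Het and of KO against WT correlated at r = 0.335 across 16836 genes, which are not independent replicates. Both contrasts share the WT libraries: 3 unchanged groups simulated in their place gave a median r of 0.496 (0.475 to 0.509). Genes were drawn independently in the simulations, while leaving out single libraries moved the observed r from 0.218 to 0.584. The simulated ranges given here do not cover genes that move together, so no conclusion is drawn from the comparison. The covariance was 0.27 against a simulated 0.343, a difference of -0.0737. At an unadjusted p under 0.05, 120 genes were higher in both contrasts (simulated median 116) and 102 lower in both (simulated median 62, range 39 to 88), where independent lists would share 12.7 and 12.9. The lists differed in length from the simulated ones, so these overlaps cannot be read as agreement: 945 genes were lower in Het (simulated median 367) and 230 lower in KO (371), 577 higher in Het (382) and 371 higher in KO (378). The same sign was seen in 68.1% of genes (simulated median 66.5%). With 3 WT libraries, the controls cannot be split so that each part keeps 2, and part of any excess may come from the shared controls.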

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

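Tests chosen only after the result was seen were those on low counts, on stroma and on blood for the Het lists, the skeletal muscle covariate for the proximal luminal list, and both tests on seminal vesicle genes.

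Of the gene lists, 5 were lower in Het than in WT while their difference between KO and Het passed in the test of that difference, camera with a preset correlation. The adjusted p was 5.4e-10 for endothelium, 4.9e-09 for fibroblasts and extracellular matrix, 2.2e-05 for blood, 3e-05 for macrophages and dendritic cells and 3e-05 for B and plasma cells, and none of the 5 passed with an estimated correlation (adjusted p = 0.31, 0.48, 0.086, 0.48 and 0.27). Both contrasts use the same Het libraries, and the 5 lists were picked for passing in both. The KO against Het calls are therefore no separate evidence. In KO against WT, fibroblasts were higher (adjusted p = 0.0044, and adjusted p = 0.69 with an estimated correlation), while the other 4 were not called (adjusted p = 0.055 to 0.71).

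The 5 lists lower in Het may follow genotype or the tissue sampled. Loss of low-count genes is raised by the lower number of genes detected in Het. The pattern was not confined to low counts: the 41 members with at least 10 CPM had a median log2 fold change of -0.67 (quartiles -1.01 to -0.49, 39 negative). This lay below all 10000 random lists matched on expression. The 5 lists were picked as lower in this same contrast, so the comparison with random lists decides nothing. The 32 members under 10 CPM had a lower median of -1.06, so low counts may add to the size. Less blood left in the vessels stays open for the blood list, since the median of the endothelium list, -1.07 (quartiles -1.39 to -0.59), restates a part of the pattern and decides nothing. Less stroma of every kind stays open: the smooth muscle score minus the endothelium score was higher by 1 (SE 0.57) in Het than in WT, with Het libraries 2 and 3 (1.4 and 1.25) above and Het library 1 (-0.38) below the WT libraries (-0.29 to -0.18), and over members smooth muscle had a median of 0.16 (quartiles 0 to 0.26) and nerve and Schwann cells 1.03 (0.21 to 1.75). A difference by genotype and a difference in dissection cannot be told apart, since the labels give neither lobes nor batches.

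Proximal luminal genes, higher in KO than in WT, could reflect genotype or neighbouring tissue taken along. The mean log2 difference of the list was 1.06 (SE 0.56). With the urothelium score as a covariate it was 0.69 (SE 0.59, camera adjusted p = 0.0028). With the skeletal muscle score it was 0.2 (SE 0.72, camera adjusted p = 0.47), and the call ended with a smaller difference and a larger error. Both stay open, since the differences are uncertain by these errors and the skeletal muscle score is itself higher in KO.

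Svs1, Svs3a, Svs3b and Sva lay near 0 in Het libraries rich in Svs2. WT library 1 showed the same, with Svs2 at 48800 CPM and these genes at 2.4, 1.99, 3.14 and 0.418 CPM. Log2 Svs1/Svs2 varied over libraries 10.2 times as much as log2 Svs5/Svs2 (SD 5.44 against 0.535), which restates the pattern. KO library 3 and Het library 3 had Svs2 at 77400 and 76000 CPM. Svs1 was at 7660 and 2.65 CPM in them, Svs3a at 2620 and 1.98, Svs3b at 2250 and 0.992, and Sva at 944 and 0. For these genes the values argue against a single seminal vesicle source of constant makeup in varying amount. Counts near the floor are argued against: at the lowest Svs1/Svs2 ratio of the KO libraries, Het libraries 1 to 3 would hold 5481, 380978 and 104663 Svs1 reads, against 0, 267 and 48 counted. At that ratio WT library 1 would hold 70902 Svs1 reads, against 46 counted. Genotype and different mixtures of lobes and seminal vesicle remain open and were not tested, with Svs1 at 2.40, 254 and 2480 CPM in the WT libraries.

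With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. In KO against WT, the real count of edgeR genes was 0 (highest other 0), which all 10 splits must match, so that it tests nothing; 1 split gave the real 14 DESeq2 genes (highest other 3) and 1 the real 15 lists (highest other 14). In Het against WT the same holds of the 0 edgeR genes (10 of 10, highest other 223), and 3 splits gave at least 205 DESeq2 genes (highest other 1016) and 8 at least 8 lists (highest other 14). The 223 edgeR genes parted WT libraries 1 and 3 and Het library 2, the libraries low in Sbp, from the rest. The 1016 DESeq2 genes parted WT libraries 1 and 2 and Het library 1 from the rest. Each is the highest of the 10 splits by its own tool, and gave more calls than the split by genotype. What these splits follow was not tested. In KO against Het it holds again (10 of 10, 0 genes, highest other 0), and 1 split gave the real 169 DESeq2 genes (highest other 104) and 3 at least 10 lists (highest other 15). For the gene-dose trend, the real count of 0 genes (highest other 0) is likewise matched by all 100 drawn splits of the 9 libraries by construction, and nothing is concluded from it.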

How the results depend on the processing

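The covariates and the fit without the 3 libraries low in Sbp were chosen after seeing the data, and the cause of each shift below was not tested. Leaving those 3 out leaves 1 WT library, assumed to vary like the other groups. In KO against WT, edgeR called 0 genes, DESeq2 14, 1 surrogate variable 1, log2(FPKM + 1) 2 with and 2 without a filter, the 6 libraries alone 1, and leaving out single libraries 0 to 1 (1 without Het library 1). In Het against WT, DESeq2 called 205, voom with quality weights 699, 1 surrogate variable 49, log2(FPKM + 0.1) 7, the seminal vesicle score 285, the fit without the 3 libraries low in Sbp 1, and leaving out single libraries 0 to 258 (258 without Het library 1). In KO against Het, no filter gave 2, DESeq2 169, log2(FPKM + 1) 1 with and 2 without a filter, log2(FPKM + 0.1) 4, the seminal vesicle score 105, the fit without the 3 libraries 1, and leaving out single libraries 0 to 18 (18 without Het library 1). The trend had 4 calls with DESeq2, 1 with 1 surrogate variable and 0 without any single library.

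Camera called 15 lists in KO against WT, 0 with an estimated correlation, 0 with fry, 7 with the seminal vesicle score, 6 with the skeletal muscle score, 9 without the 3 libraries, and 8 (without WT library 1) to 16 (without WT library 3) without single libraries. In Het against WT it called 8, 0 with an estimated correlation, 1 with fry, 5 with the seminal vesicle score, 13 with genes detected, and 6 (without Het library 3) to 13 (without WT library 1). In KO against Het it called 10, 0 with an estimated correlation, 2 with fry, 4 with the seminal vesicle score, 6 with the skeletal muscle score, and 9 (without Het library 1) to 15 (without Het library 2). Calls kept under all 9 single omissions and all 5 added settings were proliferation in KO against WT (mean difference -0.71, but -0.29 without KO library 1), macrophages and blood in Het against WT, and blood in KO against Het. Skeletal muscle in KO against WT was also kept under all 9 omissions and ended only with its own score, which is not read as a loss.

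The correlation of both contrasts with WT (0.335) was -0.182 with the seminal vesicle score, -0.191 with genes detected, and 0.218 (without Het library 2) to 0.584 (without WT library 2). No value for unchanged groups was simulated for these settings, so they cannot be set beside the simulated 0.496. In KO against WT, Srd5a2 was -2.68 with DESeq2 and -3.04 (without WT library 1) to -2.17 (without WT library 3). Wnt5a was -0.39 with the seminal vesicle score and 0.14 to 0.54 without single libraries. Lef1 was 0.58 with Sbp, 0.64 with genes detected, 0.21 without the 3 libraries, and -0.55 (without KO library 1) to 0.37 (without WT library 3). Igf1 was -0.01 with Sbp, -0.02 without the 3 libraries and 0.21 to 0.57 without single libraries. No list called in the main analysis was called in the opposite direction under another setting. For genes this could not occur, since the main edgeR analysis called 0 in each comparison. Of the gene values 10446 kept their side, 165 passed only under the alternative and 223 changed sign. Of the list values 1255 kept theirs, 169 lost the call, 75 gained one and 154 not called in the main analysis changed sign. These sign changes were counted whether or not the value passed under the alternative. Depth limits genes of few reads, such as Srd5a2 with 9 to 22 reads per KO library.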

Other observations

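The test on the neighbours of Srd5a2 was chosen only after their values were seen, as were the genes named here.

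Of the mast cell genes looked up, 3 had no reads in Het and 2 did. Mcpt4, Cma1 and Tpsb2 had 0 reads in all 3 Het libraries and averaged 3.48, 2.47 and 2.46 CPM in WT, at least 68-, 48- and 48-fold more against a floor of 3 counts over the group. The bounds cover counting error alone, as 10.7% to 12.4% of the 2383 genes averaging 1 to 3 CPM were at 0 in each Het library. Cpa3, a carboxypeptidase of mast cells, was at 0.827 CPM in Het library 3 and at 0 in the other Het libraries, against 0 to 1.06 CPM in WT. Kit, the stem cell factor receptor, which other cells also express, ran from 0.756 to 44.3 CPM in Het and from 5.45 to 14.9 CPM in WT.

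Gsdmc2, a gene of the gasdermin family, which holds pore-forming proteins, averaged 47.6 ± 23.3 CPM in KO and 5.73 ± 1.23 in WT (SD, n = 3), with an edgeR adjusted p of 1 and a DESeq2 adjusted p of 0.00765. Gsdmc3 averaged 29.0 ± 13.9 against 4.31 ± 2.55 CPM (DESeq2 adjusted p = 0.296), and Gsdmc4 was at 1.32, 2.1 and 1.83 CPM in KO against 0.314, 0 and 0.984 in WT (DESeq2 adjusted p = 1). KO library 2 had the highest values of Gsdmc2 (71.2 CPM), Krt4 (145 CPM) and Clca1 (15.7 CPM), and also the highest skeletal muscle score (5.04). Reads shared between the Gsdmc paralogs cannot be told apart.

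Ehd3, an endocytic recycling protein, has its lowest coordinate at -213 kb from that of Srd5a2. It was at 2.74, 6.14 and 5.12 CPM in KO, 2.75, 3.03 and 3.14 CPM in Het and 0.732, 1.46 and 0.622 CPM in WT. Its log2 fold change was 2.30 (SE 0.54, edgeR adjusted p = 1) in KO against WT. Capn13, a calpain at -710 kb, had 2 (SE 0.63, adjusted p = 1). Srd5a2 lies on the minus strand, so both genes are on its downstream side. A hypothesis is that the altered allele, or DNA linked to it, may affect genes along the chromosome. Of 16 tested genes within 1000 kb, 2 had an unadjusted p under 0.05, and 23.9% of 16835 windows around other genes held as many, so the test leaves the hypothesis open.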
